A study of Rattus norvegicus with 12 samples.

How the data were processed

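Total RNA of the right trigeminal ganglion was sequenced in 12 samples from female Sprague Dawley rats, 3 for each of 4 capsule groups (vehicle, 5%, 20% and 40% E2) after 1 week. Per the labels' protocols, RNA was extracted with a Qiagen kit, samples of high integrity were made into libraries with the NEBNext Ultra kit, and these were sequenced on an Illumina instrument by Novogene. The submitters' processing notes name CASAVA, fastp, HISAT2, featureCounts and DESeq2, without versions, roles or order. The genome build, the gene annotation and whether counting used strand are not given in the sources used here. That kit, as named, does not say whether strand was kept, so reads of overlapping or antisense genes may be counted for the wrong gene. How reads that match near-identical genes were counted is not given either. The labels give 3 samples per group but do not tie each one to an animal of its own, though the series design gives 3 per treatment group, so p-values measure the spread between these samples.

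The deposited files hold FPKM values for each library, per the names of the deposited files, computed by the authors. The planned test assumed raw counts and was a quasi-likelihood count test. Because the files hold FPKM, limma was used in its place on log2(FPKM + 1). A table of the whole series holds the FPKM values of the same 12 libraries under a header that does not line up with its columns, and was not used. Genes with an FPKM of at least 1 in at least 3 libraries were tested (14781 of 32545). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

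Depth was recovered from the values. Each FPKM is a whole number of fragments divided by the gene's length and by a denominator of the library, and values are printed with up to 10 digits and 9 decimals. The low genes give the libraries' relative depth, and the requirement that lengths and fragments be whole gives the rest. All 21071 genes above 0 in at least 2 libraries came out whole (largest deviation from a whole number 8.94e-05 over 219665 values). A length was accepted only if it gave whole numbers within a tolerance, which bounds that deviation. In simulated data 100% of 20076 genes were recovered exactly. These were longer than the shortest models named below and were above 0 in more than 2 libraries, so the simulation does not cover the shortest or sparsest genes. Fragments and lengths are the smallest whole numbers that fit, so a low gene may have a multiple of both. The recovered totals were 13281981 to 16978830 fragments, a range of 1.28-fold. The authors' denominators differed from these totals by −1.02% to 2.53%, and by −0.02% to 0.29% from totals scaled by median-of-ratios size factors. A floor of 3 fragments and all counts cover counting error only, since fragments without molecular identifiers are not independent molecules. The FPKM filter kept 810 genes with models under 200 bases and 1770 genes averaging under 30 fragments per library.

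All 12 libraries entered 1 limma-trend fit of the 4 group means, with robust empirical Bayes moderation of the variance, and each comparison is a contrast in it. A moderated F-test asked for any difference among the 4 groups, and a separate fit used the slope on E2 percent (0, 5, 20, 40). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The separation of the groups was tested on root mean square distances with an exact permutation test, one-sided, over every partition. The fit was tested on simulated negative binomial fragments drawn from the recovered means and depths, with a spread averaged over genes of similar level. In 3 draws per comparison, 200 genes were changed by 1.25-, 1.5-, 2-, 3- or 4-fold. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 7.58 or more), so each counted as 1 replicate.

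The plan named genes by a rule fixed before the data were examined: up to 12 genes each way past the threshold with the 2 groups not overlapping (up to 6 each way between doses), and otherwise the genes of smallest p up to 10, given as not passing. It asked for a mean log2 CPM of at least 0. The rule also needed gene symbols, as did 16 genes fixed in advance (estrogen and serotonin receptors and sensory neuron genes among them) and 42 gene lists. None of the 32545 identifiers matched the reference table of 47357 genes of assembly GRCr8, which carries no Ensembl identifiers, so the fixed genes and lists were not analysed here. The 3 genes past the threshold therefore fall outside the rule, ENSRNOG00000054324 for its low level too. They are given by identifier and were chosen after their values were seen, as were the other leading genes, which are described by their values without the floor on expression.

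Alternatives chosen in advance were another pseudocount (0.1), no filter on low values, a stricter filter (1 CPM in at least 3 libraries), limma's voom with sample quality weights on the recovered fragments, a fit on the compared groups alone, the replicate number as a block, an adjusted p of 0.1, a fold of at least 1.5, the rank of the dose, and leaving out each library. The plan assumed raw counts, so the pseudocount on FPKM and voom on recovered fragments took this form once the files proved to hold FPKM. Chosen after seeing the data were voom without weights, scaling by library total or by size factors, a residual principal component as a covariate, a minimum mean of 30 recovered fragments, and leaving out genes with 2 levels inside groups. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.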

Results

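RNA was profiled in the right trigeminal ganglion, the ganglion that holds the cell bodies of the sensory neurons of the face and meninges, of female Sprague Dawley rats that had carried a hormone capsule for 1 week. The 12 libraries fall into 4 groups of 3. Vehicle capsules held 100% cholesterol. The others held estradiol (E2), the main ovarian estrogen, at 5%, which the labels equate with the level of diestrus, the phase of low estrogen in the rat cycle, at 20%, equated with proestrus, when estrogen peaks, or at 40%, called a therapeutic level. The series asks how the dose of E2 alters the way trigeminal sensory neurons respond to serotonin, and the libraries allow each dose to be compared with vehicle, the doses with one another, and all 4 groups along the dose. The deposited values are FPKM (fragments per kilobase of gene model, scaled to library depth) for 32545 Ensembl rat genes, of which 9724 were listed at 0 in every library. A depth of 13281981 to 16978830 fragments per library was recovered from the values themselves. It averaged 15768300 ± 1915513 fragments (SD, n = 3) in the vehicle group, 15683895 ± 453423 at 5% E2, 14690692 ± 1931795 at 20% E2 and 13474510 ± 284974 at 40% E2. At these depths 3 fragments correspond to between 0.177 and 0.226 CPM (counts scaled to library depth), and 14781 genes reached an FPKM of 1 in at least 3 libraries and were tested. The files do not pair the gene identifiers with names, so genes are given by identifier, and receptor, channel, glial or immune genes could not be singled out.

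The 4 groups were not detectably farther apart than groups drawn at random from the same libraries. Between-group differences made up 27.5% of the squared distance among the 12 libraries, where 27.3% is the average of random groups, and the exact permutation test over all 15400 ways of forming 4 groups of 3 gave p = 0.375. One vehicle library stood apart. Vehicle replicate 1 differed from the other 11 by a mean of 0.497 (root mean square difference on the log2(FPKM + 1) scale), against 0.427 to 0.455 for the others, and had the fewest genes above 0 (17843, against up to 18836) although it was the deepest library. Without it, between-group differences made up 30.2% of the squared distance, against 30% for random groups (exact permutation p = 0.387).

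**Figure D1:**
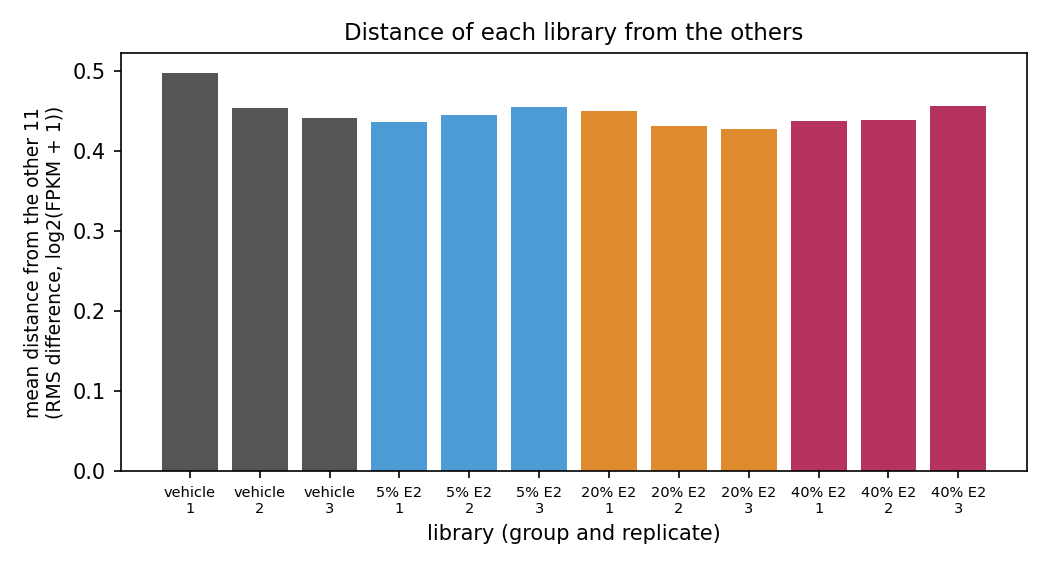
Mean distance of each of the 12 libraries from the other 11, as the root mean square difference on the log2(FPKM + 1) scale, 1 bar per library, coloured by group. Vehicle replicate 1 reached 0.497 and the other 11 lay between 0.427 and 0.455.

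At 5% E2, no gene passed the threshold against vehicle (limma adjusted p under 0.05). The gene with the smallest p was ENSRNOG00000050800, with 12.7 ± 4.54 FPKM (SD, n = 3) at 5% E2 against 2.97 ± 0.882 in vehicle, a log2 difference of 1.75 ± 0.29 (SE) with a limma adjusted p of 0.495. All 3 libraries at 5% E2 lay above all 3 vehicle libraries, with 1032 fragments in total against 253. The next gene by p had a recovered model of only 96 bases, and its values of 9.60 ± 5.31 FPKM against 0.206 ± 0.357 stood for 43 recovered fragments against 1. A longer gene, of 3472 bases, had 39.9 ± 1.495 FPKM at 5% E2 and 53.5 ± 1.52 in vehicle (log2 difference −0.41, adjusted p = 0.592). Of the 10 genes with the smallest p, 6 had higher and 4 lower values at 5% E2. In all 10 the 2 groups did not overlap, which adds no support, since genes picked by smallest p were separated in every comparison. By limma-trend, 812 of the 14781 genes (5.49%) had an unadjusted p under 0.05, 370 higher and 442 lower. Limma's voom on the recovered fragments also called 0 genes, with and without sample weights, with 825 and 875 at an unadjusted p under 0.05. Leaving out vehicle replicate 3, or 5% E2 replicate 3, gave 1 call with higher values at 5% E2. Leaving out 5% E2 replicate 2 gave 1 with lower values. ENSRNOG00000050800 was not among these calls (limma adjusted p 0.0944 to 0.907 over the alternatives).

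At 20% E2, 1 gene passed the threshold with lower values than in vehicle, and none passed with higher values. The gene was ENSRNOG00000054324, at 6.78 ± 3.00 FPKM (SD, n = 3) in vehicle and listed at 0 in all 3 libraries at 20% E2. Its log2(FPKM + 1) difference was −2.89 ± 0.32 (SE), with a limma adjusted p of 0.0226. That value depends on the pseudocount, since the gene is at 0 in 1 group, and ranged from −6.02 with log2(FPKM + 0.1) to −2.60 over the alternatives. Set against a floor of 3 fragments in each library, it was at least 2.62-fold lower. The smallest length that fits its values is only 79 bases, at which the vehicle values stood for 14, 6 and 6 fragments. At 5% E2 it had 2.16 ± 0.947 FPKM. The next gene by p went the other way, from 0 in all vehicle libraries to 3.00 ± 0.654 FPKM, on 8 fragments of a 60-base model (adjusted p = 0.166). Among longer genes, one of 3271 bases had 31.1 ± 0.940 FPKM at 20% E2 and 20.9 ± 1.47 in vehicle (log2 difference 0.55, adjusted p = 0.675). The ENSRNOG00000054324 call was lost with either voom fit, which called 0 genes with 1041 (weighted) and 940 (unweighted) at an unadjusted p under 0.05. It was also lost without vehicle replicate 1 or 2, without 5% E2 replicate 1, without any 1 of the 20% E2 libraries, with log2(FPKM + 0.1), with no filter on low values, with the compared groups alone, and when genes under 1 CPM or averaging under 30 fragments per library were left out, each of which gave 0 calls (adjusted p 0.00953 to 0.704 over the alternatives that keep the gene). Without vehicle replicate 3 or 5% E2 replicate 2 there were 2 calls, this gene among them. Under limma-trend 897 genes (6.07%) had an unadjusted p under 0.05, 451 higher and 446 lower.

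At 40% E2, no gene passed the threshold against vehicle. ENSRNOG00000054324 again had the smallest p, with 0.314 ± 0.545 FPKM (SD, n = 3) against 6.78 ± 3.00 in vehicle (log2 difference −2.57 ± 0.32 SE, limma adjusted p = 0.0737). Leaving out 40% E2 replicate 1, the library with its single fragment in that group, gave 1 call (adjusted p = 0.0280, with a range of 0.0280 to 0.593 over the alternatives). With the compared groups alone, 1 other gene was called, with lower values at 40% E2. The gene next by p, with a model of 657 bases, had 2.24 ± 0.265 FPKM against 7.11 ± 2.01 in vehicle (log2 difference −1.30, adjusted p = 0.344). A gene of 3826 bases had 2.87 ± 0.493 FPKM against 0.618 ± 0.0865 (log2 difference 1.253, adjusted p = 0.344). Of the 10 genes with the smallest p, 3 had higher and 7 lower values at 40% E2. By limma-trend, 867 genes (5.87%) had an unadjusted p under 0.05, 418 higher and 449 lower, and voom called 0 genes, with 808 (weighted) and 847 (unweighted).

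**Figure D2:**
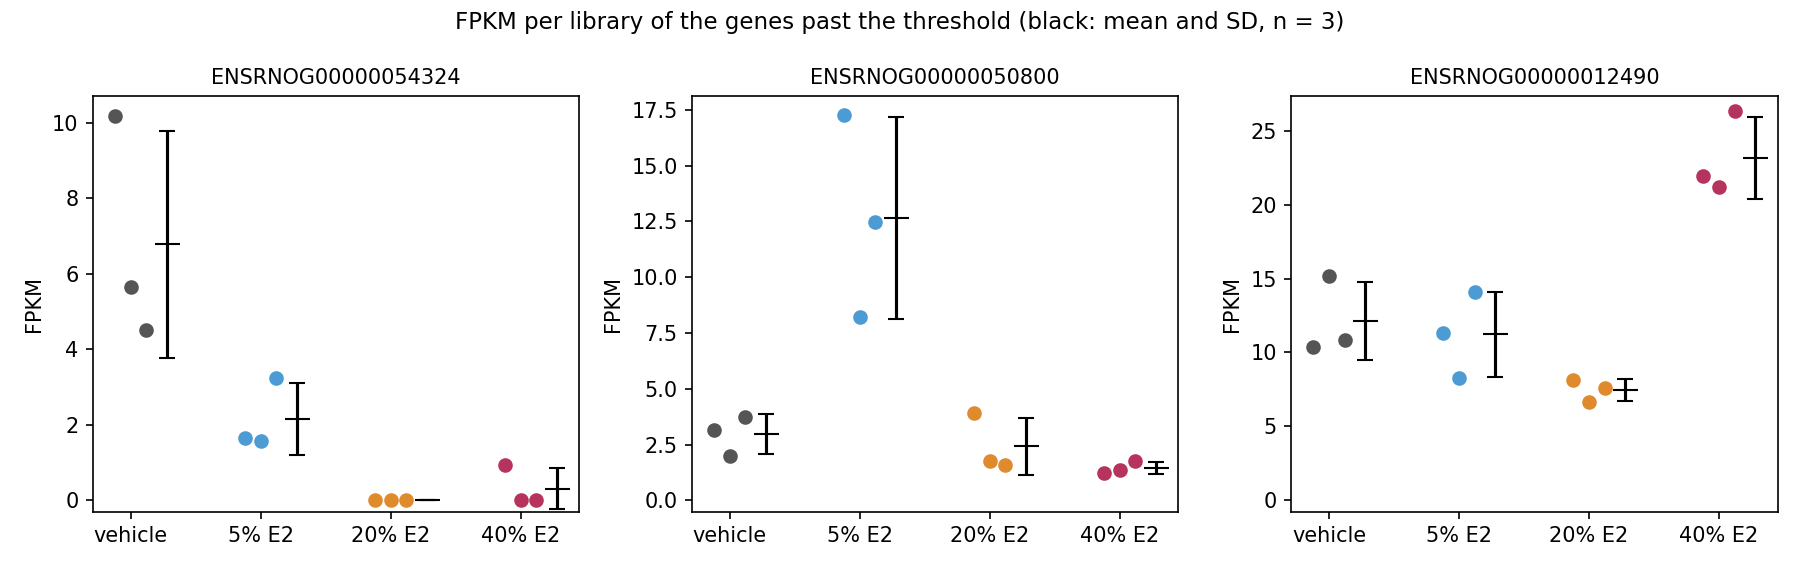
FPKM of ENSRNOG00000054324, ENSRNOG00000050800 and ENSRNOG00000012490 in each of the 12 libraries, grouped by capsule, with the mean and SD of each group of 3 in black. ENSRNOG00000054324 is listed at 0 in all 3 libraries at 20% E2, ENSRNOG00000050800 averages 12.7 FPKM at 5% E2 and at most 2.97 in any other group, and ENSRNOG00000012490 averages 23.2 FPKM at 40% E2 and at most 12.1 in any other group.

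The doses were also compared directly, and 2 genes passed, each in 1 pair, with p adjusted within each pair alone. Neither passed the limma F-test over all 4 groups (adjusted p = 0.111 for ENSRNOG00000050800 and 0.117 for ENSRNOG00000012490). ENSRNOG00000050800 fell from 12.7 ± 4.54 FPKM (SD, n = 3) at 5% E2 to 1.45 ± 0.261 at 40% E2, a log2 difference of −2.43 ± 0.29 (SE, limma adjusted p = 0.0423). At 20% E2 it had 2.42 ± 1.29 FPKM, a log2 difference from 5% E2 of −2.01 (adjusted p = 0.271). ENSRNOG00000012490 rose from 7.46 ± 0.752 FPKM at 20% E2 to 23.2 ± 2.77 at 40% E2, a log2 difference of 1.51 ± 0.18 (adjusted p = 0.0380). It had 12.1 ± 2.65 FPKM in vehicle and 11.2 ± 2.89 at 5% E2, and against vehicle neither 20% E2 (log2 difference −0.62, adjusted p = 0.785) nor 40% E2 (0.89, adjusted p = 0.344) passed. Its gene model is 2248 bases long and its 40% E2 values rested on 658 to 799 fragments per library. These were the only calls among the 3 dose pairs by limma-trend: 20% against 5% E2 gave 0 calls, with 662 genes at an unadjusted p under 0.05, 40% against 5% E2 gave 1, with 666, and 40% against 20% E2 gave 1, with 429. The ENSRNOG00000012490 call was also made by voom with and without sample weights, and the ENSRNOG00000050800 call by neither (adjusted p = 0.136 with weights and 0.236 without). With no filter on low values both calls were lost (adjusted p = 0.0992 for ENSRNOG00000012490 and 0.174 for ENSRNOG00000050800). The ENSRNOG00000050800 call was also lost with the compared groups alone (0.0780), with a residual component as a covariate (0.135) and with scaling by library totals (0.0503). For 40% against 5% E2, weighted voom called 2 other genes and unweighted voom 0. For 20% against 5% E2 both called 0, with 1285 and 649 at an unadjusted p under 0.05.

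Leaving out single libraries ended both dose-pair calls in most cases while the log2 differences stayed between −2.68 and −2.19 for ENSRNOG00000050800 and between 1.42 and 1.57 for ENSRNOG00000012490. The ENSRNOG00000050800 call held without 5% E2 replicate 2 or 20% E2 replicate 1 and was lost without any other single library, the adjusted p ranging from 0.0127 over the alternatives to 0.403 without 40% E2 replicate 1. Without 40% E2 replicate 2, 1 gene was called in its place. The ENSRNOG00000012490 call held without vehicle replicate 2 and without 5% E2 replicate 2 or 3, and was lost without any other single library, its adjusted p ranging from 0.000367 with weighted voom to 0.361 without 20% E2 replicate 2. Without 20% E2 replicate 1 or 3 that comparison called 1 gene in its place, and without 5% E2 replicate 2 it gave 2 calls. Without 5% E2 replicate 2, 5 genes passed between 20% and 5% E2, where 20% E2 replicate 1 left out gave 2 and 20% E2 replicate 3 left out gave 1.

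Over all 4 groups together, no gene passed the threshold (limma F-test, smallest adjusted p = 0.0795, for ENSRNOG00000054324), with 708 genes at an unadjusted p under 0.05. Either voom fit called 1 gene, with 825 (weighted) and 666 (unweighted) at an unadjusted p under 0.05. Without 5% E2 replicate 2 the F-test called 5 genes, and without 40% E2 replicate 1 it called 1. A linear trend over E2 percent was found for no gene (smallest adjusted p = 0.346), with 881 at an unadjusted p under 0.05, 421 with a positive and 460 with a negative slope. Voom called 0 genes for the trend, with 809 (weighted) and 889 (unweighted). The gene leading the trend, with a model of 740 bases, had 26.5 ± 3.67 FPKM (SD, n = 3) in vehicle and 17.5 ± 2.31 at 40% E2. Of the 10 genes with the smallest trend p, 8 had a negative and 2 a positive slope, none past the threshold.

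**Figure D3:**
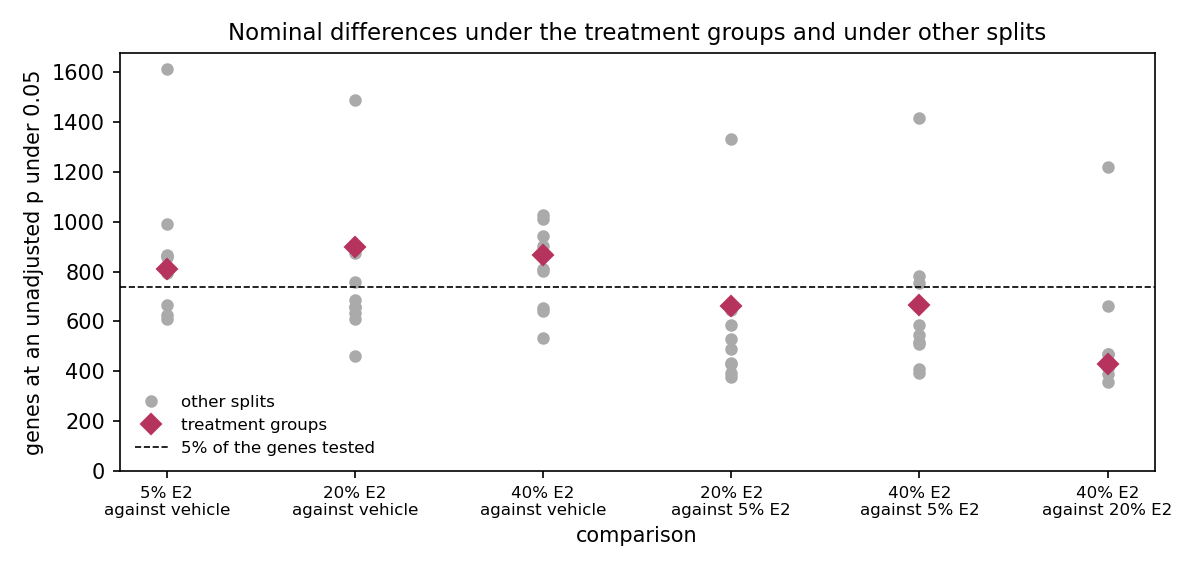
Number of genes at an unadjusted p under 0.05 in each pairwise comparison, for the treatment groups (diamonds) and for the 9 other ways of splitting the same 6 libraries into 3 and 3 (grey points), with 5% of the 14781 genes tested as a dashed line. The treatment groups gave between 429 and 897 genes and lay below the highest other split in all 6 comparisons.

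Fold changes of the 3 doses against vehicle were compared with those that the shared vehicle libraries give alone. Across genes, which are not independent replicates, the log2 differences of 5% and 20% E2 had a covariance of 0.0378 (correlation 0.539), where simulated unchanged groups against the same vehicle libraries gave a covariance of 0.0385 (correlation 0.551). For 5% and 40% E2 the covariance was 0.0393, against 0.0387 simulated. For 20% and 40% E2 it was 0.0446 (correlation 0.610), against 0.0386 simulated (correlation 0.551), near the top of the 0.0325 to 0.0453 of the 200 draws. The share of genes with the same sign was 73.4% for that pair, against 67.9% simulated. The overlap of calls was 0, which was fixed in advance because 5% and 40% E2 had 0 calls each against vehicle. At an adjusted p of 0.1 it was 1. With 3 vehicle libraries the controls could not be split, and part of any excess may come from them.

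The fit gave each pair of groups the same precision, since all 12 libraries shared 1 estimate of the spread. The sample weights of voom were 0.351 for vehicle replicate 1 and 0.763 to 1.83 for the others. Comparisons with vehicle may therefore be less precise than the fit states. The median gene had a standard error of 0.13 on the log2(FPKM + 1) scale. For 20% and for 40% E2 against vehicle, the 95% confidence interval of 88.9% of genes lay within 1 unit of 0 on that scale. For low genes 1 unit can be more than a 2-fold change in FPKM, so such changes are not excluded for them. When 200 genes at once were changed in simulated libraries of the same depth, limma-trend found 77.5% of genes changed 2-fold at 5% E2, 71.7% at 20% E2 and 67.5% at 40% E2. Of 1.5-fold changes it found 50%, 32.5% and 40.8%. These shares hold for that number of changed genes, since the adjusted p depends on it. In the simulation, genes of similar level shared 1 spread and no library was made noisier than the rest. The shares may therefore overstate what these data could detect. Over the 3 simulated draws of each comparison, 9, 23 and 17 unchanged genes were called as well.

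**Figure D4:**
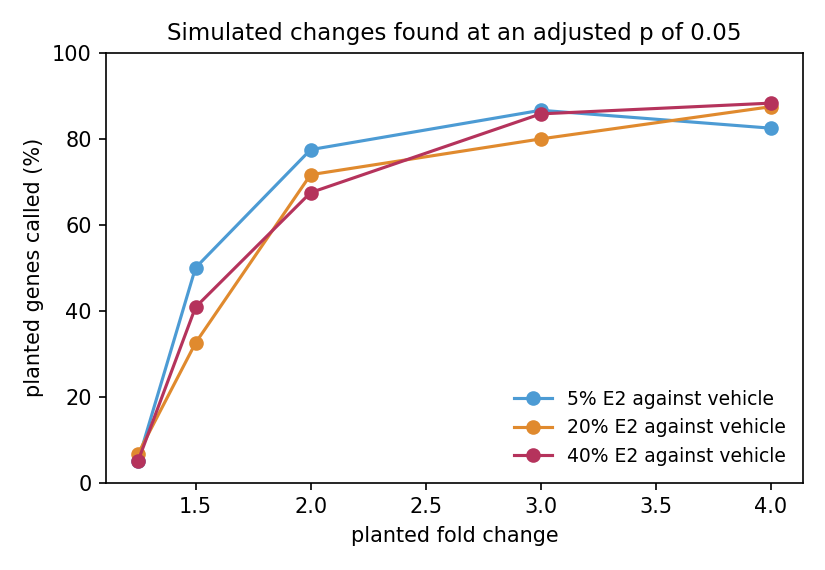
Share of planted changes that limma-trend called at an adjusted p of 0.05 (vertical axis, percent) against the planted fold change (horizontal axis), for each dose against vehicle, 120 planted genes per point. At 2-fold the 3 doses gave 77.5%, 71.7% and 67.5%, and at 1.5-fold 50%, 32.5% and 40.8%.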

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

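The counts over other splits, the gene length test and the use of weighted voom and of the trend to weigh explanations were chosen after the results were seen. For 2 genes the effects of a pair of doses differed when the doses were tested against each other. ENSRNOG00000050800 differed between 40% and 5% E2 by a log2 change of −2.43 (adjusted p = 0.0423, −3.05 to −2.19 and adjusted p 0.0127 to 0.403 over the alternatives), with all 3 libraries at 40% E2 below all 3 at 5% E2. ENSRNOG00000012490 differed between 40% and 20% E2 by 1.51 (adjusted p = 0.0380, 1.42 to 1.63 and adjusted p 0.000367 to 0.361 over the alternatives), with all 3 libraries at 40% E2 above all 3 at 20% E2. Such separation adds no support, since all 10 genes of smallest p were separated in every pair of groups, also in pairs with 0 calls.

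Every count of calls was set against other splits of the same libraries. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For 5% E2 against vehicle the real split gave 0 calls and the highest other 3, and all 10 gave as many as the real one. For 20% E2 against vehicle the values were 1 and 1, with 3 of 10 splits as high, and for 40% E2 against vehicle 0 and 1, with 10 of 10. For 20% against 5% E2 they were 0 and 1, with 10 of 10, for 40% against 5% E2 1 and 2, with 3 of 10, and for 40% against 20% E2 1 and 2, with 3 of 10. For any difference among the 4 groups, the real split gave 0 calls and the highest other 4, and for the trend 0 and 2. All 100 splits drawn give at least 0 calls in either case, so that these counts decide nothing about chance. At an unadjusted p under 0.05, the real split and the median of the others gave 812 and 858 genes for 5% E2 against vehicle, 897 and 659 for 20% E2, 867 and 811 for 40% E2, 662 and 491 for 20% against 5% E2, 666 and 545 for 40% against 5% E2, 429 and 440 for 40% against 20% E2, 708 and 626 for any difference, and 881 and 720 for the trend. Counting the real split, 6, 2 and 5 of 10 gave as many for 5%, 20% and 40% E2 against vehicle, 2 of 10 for 20% against 5% E2, 4 of 10 for 40% against 5% E2, 7 of 10 for 40% against 20% E2, 35 of 100 for any difference and 29 of 100 for the trend.

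ENSRNOG00000054324, the 1 gene called at 20% E2 against vehicle, rested on 26 fragments in the vehicle libraries and 0 at 20% E2. Counting noise alone is argued against by the pooled fragments, with an exact binomial p of 0.000615 (two-sided) after multiplying by the genes tested. With voom, which weights by fragments, its adjusted p was 0.512 with sample weights (0.00953 to 0.704 over the alternatives). The log2 difference was −3.82 ± 0.87 (SE) with weighted and −4.00 ± 0.93 with unweighted voom, against −2.89 ± 0.32 with limma-trend. With voom the call thus ended with a larger SE and not with a smaller fold, although folds against libraries at 0 depend on the offset of each method. Over the alternatives the log2 difference ranged from −6.02 to −2.60. An error estimated as too small on the FPKM scale, where a 79-base model turns few fragments into high values, may have made the call and stays open. An effect of E2 dose stays open, since the trend over E2 percent had an adjusted p of 0.555 and a p that misses the threshold excludes nothing.

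Vehicle replicate 1 stood apart from the other libraries by a mean distance of 0.497, and on the first principal component (13.7% of the variance) it lay at −43.7 where the others lay between −1.28 and 11.4. Depth and a shortage of fragments in low genes are argued against: with every library thinned to the shallowest, its mean distance was 0.503 and the highest other 0.461, and over the 3696 genes with the most fragments it was 0.253 and the highest other 0.220. A bias shared by genes of similar length is argued against by a distance of 0.495 after removing deviations by length class, where the highest other was 0.454. The same removal took length trends planted in the other 11 libraries, each sized to reach 0.497, back to between 0.426 and 0.454. Those trends depended on length alone, so a bias that varies among genes of similar length was not tested. The design gives no biological explanation for a single vehicle library and none was tested, and a difference in dissection or RNA handling stays open as untested.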

How the results depend on the processing

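The alternatives added after seeing the data are voom without weights, the 2 rescalings, the residual component, the minimum of 30 fragments and the removal of genes with 2 levels. Scaling by size factors nearly repeats the main fit, since the authors' denominators differed from those totals by −0.02% to 0.29%. The 5% E2 against vehicle and 20% against 5% E2 counts stayed at 0 under all alternatives other than leaving out a library. For 20% E2 against vehicle, the 1 call became 0 with log2(FPKM + 0.1), either voom fit, no filter, the stricter filter, the compared groups alone, the replicate block and the minimum of 30 fragments. The stricter filters leave out ENSRNOG00000054324 by construction, and elsewhere the cause was not tested. For 40% E2 against vehicle, the 0 became 1 at an adjusted p of 0.1, where the gene was ENSRNOG00000054324. It also became 1 with the compared groups alone, through another gene, since ENSRNOG00000054324 had a limma adjusted p of 0.292 there. For 40% against 5% E2, the 1 call became 2 with weighted voom and 0 with unweighted voom, no filter, the compared groups alone, the residual component and scaling by library totals. For 40% against 20% E2, the 1 became 0 with no filter and with the replicate block. The F-test over the 4 groups gave 1 at an adjusted p of 0.1 and with either voom fit, and the trend gave 1 with the residual component. The overlap of calls between doses became 1 at an adjusted p of 0.1. Leaving out 1 library gave 0 to 1 calls for 5% and for 40% E2 against vehicle, 0 to 2 for 20% E2 against vehicle, 0 to 5 for 20% against 5% E2, 0 to 1 for 40% against 5% E2, 0 to 2 for 40% against 20% E2, 0 to 5 for the F-test and 0 for the trend. No named gene reversed its direction. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between −0.05 and 0.08 across genes in 18 pairs, and a library correlated best with its own number in 13 of 36 tries. With the number as a block, counts were 0, 0 and 0 against vehicle, 0, 1 and 0 between doses, and 0 for the F-test and the trend. The other planned count tests and a surrogate variable were not run on values deposited as FPKM, and the gene-list tests were not run for lack of gene symbols. Of the 14781 genes tested, 1770 averaged under 30 fragments per library, and how far depth limited them was not tested.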

Other observations

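The tests in this part were chosen after the pattern was seen. Some genes took 2 separate levels among samples of the same group. Of 13011 tested genes averaging at least 30 fragments per library, 36 had a gap of at least 1 on the log2(FPKM + 1) scale, wider than the range on either side and with at least 3 libraries on each side, the median gap being 2.04 and the widest 3.89. In all 36 at least 2 treatment groups held both levels, and for 0 of them did the gap separate whole groups. Counting noise is argued against, since the most such genes in any of 20 draws of counting noise was 0, and normal noise with each gene's own spread gave at most 4. A single factor that splits the libraries in the same way for most of these genes, such as the makeup of the dissected tissue, is also argued against. The most common split of the libraries held 3 genes (8.33%). Splits placed at random held at most 3 in 1000 draws, so a cause shared by those 3 genes stays open. Only identical splits were counted, so a factor that gives similar splits was not tested. The 36 genes divided the libraries in 34 different ways. That is consistent with variants carried by some of the animals, Sprague Dawley rats being an outbred stock, and equally with any influence that acts on each gene separately. The reads, which could show such variants, were not used here.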
